A study of Mus musculus with 8 samples.

How the data were processed

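RNA from 8 samples of sorted mouse OT-1 CD8+ T cells was measured on Illumina mouse-ref8-v2.0 beadchips, per the labels. Each sample was assigned to its group and replicate number from its title: 4 arrays of cells stimulated by CD40-activated B cells (cB) and 4 of cells stimulated by dendritic cells (DC). Nothing in the labels says that the replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

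The deposited non-normalized table holds the average bead signal, an intensity on a linear scale, for 18138 gene names on each array, per the file headers. The same deposited table gives a detection p-value for every gene on every array, per the file headers. The authors also deposited normalized log2 values for 7266 genes and for 10578 probes; their method is not given in the sources used here. The deposited value table of the series held the same numbers as the probe-level table, with a largest difference of 0. The probe-level table carries no gene names, so it gave counts of probes only. In the authors' gene-level values 8 names had been turned into dates, and 7258 genes were found in the non-normalized table.

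Gene names in the table are those of the array design. Of these, 14309 matched a current symbol and 2641 a synonym in the RefSeq gene table of assembly GRCm38.p6, which was used for names only. A gene name stands for 1 row of the table, so probes of a gene could not be compared.

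Log2 values were computed from the intensities with limma 3.58.1 in R 4.3.3. The background of each array was estimated from the detection p-values, normexp correction was applied with an offset of 16, and arrays were quantile normalized. The detection p-values of 13929 genes were whole multiples of 1 part in 798 on all arrays, within a tolerance of 0.001 of a step, as ranks among 798 negative controls would be. The other 4209 genes were not on this step. The background was estimated from the genes on the step, which gave a negative-control SD between 15.1 and 25.4 intensity units per array. With limma's default, which uses all genes, the estimated SD was between 195 and 344. The restriction was made the main setting after results under the default had been seen, on the basis of these SDs, and the default is kept as an alternative. Both settings, no correction and the authors' values give different sizes for the changes of dim genes. Many of these shifts, not all, are stated beside the results. The background from all genes often gave the smallest sizes for dim genes.

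Genes with a detection p below 0.05 on at least 4 of the 8 arrays were tested, which left 7167. The comparison was cB minus DC, fitted with limma's lmFit and eBayes, with the Benjamini-Hochberg adjusted p below 0.05 as threshold. A count with a log2 difference of at least 1 in size was kept beside it. All log2 differences are cB minus DC and are given with the standard error (SE) of the fit over 4 arrays per group. A gene undetected on all 4 arrays of a group has only a bound there. Under this background setting its fold is given as "at least", from the bright group's mean over the mean of, per array, the higher of the lowest detected value and the gene's own value.

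Before the data were examined, 25 gene lists with 668 entries were fixed, of which 606 entries were in the table and 428 were tested. Lists were tested two-sided with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated from the residuals. At the preset correlation 9 lists passed, and 3 of these, cell cycle, sterol and fatty acid synthesis, and apoptosis, passed with the estimated correlation. Of the 25 lists 22 passed fry, which tests whether a list's genes move on balance one way and does not compare a list with other genes. The genes named were fixed by rule: the 10 largest differences in each direction among called genes with a symbol and no overlap between groups, up to 4 members of each list by lowest p, the brightest member of each list of foreign-cell markers, and Cd69, Cd8a, Ifng, Il2, Tnf, Gzmb, Prf1, Il2ra and Pdcd1. Il2 was not analysed here, and some other genes the rule takes are not reported here. Some further members are named in the text as examples of a list's count and were chosen after their values were seen. Lists of p53 targets, lysosome and autophagy genes, NRF2 targets and core histones were written after the values had been seen.

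The procedure was tested on simulated data with 8411 genes passing the detection filter, of which 200 had been changed. It called 32% of the 50 genes changed by 0.5 on the log2 scale, 72% at 1, 98% at 2 and 100% at 4. It called 17 unchanged genes, 10.1% of all calls, which is above the share aimed at by the threshold. This was a single run with 200 genes changed, whereas 61.4% of the genes tested in the real data passed the threshold. The shares called and the share of false calls depend on that proportion, so they do not carry over to the real calls. A list of 25 genes, all raised by at least 1, passed camera, which was built in, and 0 of 20 random lists did. The noise was drawn for each gene alone, so the random lists do not test camera where genes are correlated. The changed genes were taken from the brighter ones, so the shares called do not cover dim genes.

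Alternatives were the replicate number as a block, cyclic loess, no background correction, equal medians, the authors' tables, other detection filters, a trended and robust variance, array weights, a stricter threshold and leaving out each array. Figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision. Between 6945 and 7393 genes were detected per array.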

Results

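The series measured gene expression in OT-1 cells, mouse CD8+ T cells whose receptor recognizes the ovalbumin peptide SIINFEKL on H2-Kb. The T cells had spent 24 h at a 5 to 1 ratio with peptide-loaded, LPS-matured antigen-presenting cells, either B cells activated through CD40 (cB) or dendritic cells (DC), and those positive for CD8 and the activation marker CD69 were sorted. There were 4 arrays per group. Mean intensity per array ranged from 602 to 824, and between 38.3% and 40.8% of the genes were detected on an array. The comparison asks how T cells activated by the 2 kinds of stimulator differ.

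The groups differed widely. Ifng, which encodes interferon-gamma, was 158-fold higher in cB-stimulated cells (log2 difference 7.31 ± 0.30, SE, n = 4 per group), and genes of cell division and of sterol synthesis were higher there almost without exception. In DC-stimulated cells, most of the tested early T cell receptor response genes, interferon response genes and regulators of apoptosis and survival were higher. Of these lists, only that of apoptosis and survival passed camera with an estimated correlation. Of 7167 genes tested, 4397 (61.4%) passed the threshold, 2134 higher in cB and 2263 higher in DC. The 2 groups did not overlap in 4074 genes (56.8%, where chance gives 2.86%). The median log2 difference over all genes was -0.03. The first principal component held 85.7% of the variance and separated the groups, and on the second (4.33%) cB replicate 4 stood apart at -23.1; array correlations lay between 0.979 and 0.990 within groups and between 0.863 and 0.883 across them. Of the called genes, 1755 differed by at least 2-fold, 864 higher in cB and 891 higher in DC. This size-filtered count rested on the background estimate: it was 923 with no background correction, 960 in the authors' gene-level table and 962 with the background from all genes.

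By estimated difference Ifng was first toward cB, and the next 9 genes follow here. The rank of a gene given only a bound is not fixed, in either direction. Pclaf, which encodes a PCNA-binding protein, was at least 110-fold higher, and Mcm10, a replication initiation factor, at least 66.2-fold; neither was detected on any DC array. Pbk, a mitotic kinase gene, was at least 73.0-fold higher and Rad54b, a DNA repair gene, at least 48.6-fold. Top2a (DNA topoisomerase) differed by 6.31 ± 0.20, Birc5 (survivin) by 6.30 ± 0.16, Prc1 by 5.69 ± 0.19, Kif22 by 5.68 ± 0.19 and Plk1, a mitotic kinase gene, by 5.61 ± 0.25. Top2a, Kif22 and Plk1 were each detected on 1 of the 4 DC arrays and Prc1 on 3, so their DC levels lie near background. Toward DC, the largest differences were in the linker histone gene H1f2 at -5.23 ± 0.24, Dcxr at -5.15 ± 0.20, the acyl-CoA thioesterase gene Acot1 at -5.03 ± 0.35 and Osr2 at -4.83 ± 0.18. Ak1, an adenylate kinase gene, was at least 24.6-fold higher in DC. Zfp750 (-4.73 ± 0.16), the p53-induced gene Trp53inp1 (-4.65 ± 0.33), Bbs7 (-4.56 ± 0.12), the protease inhibitor gene Serpine2 (-4.52 ± 0.24) and the TGF-beta co-receptor gene Eng (-4.39 ± 0.18) followed. On the cB arrays Zfp750 was detected on 1 of 4, Acot1 on 2, and Osr2 and Bbs7 on 3 each. These sizes, and the bounds given as "at least", hold for the background setting used here, which gave larger differences for dim genes than no correction, the authors' gene-level table or the background from all genes. In the authors' gene-level table the differences of Ifng, Pclaf, Mcm10, Pbk, Rad54b, Top2a, Prc1, Kif22, Plk1, Dcxr, Osr2, Ak1, Zfp750, Bbs7 and Eng were 5.73, 4.61, 3.94, 4.06, 3.51, 4.21, 3.81, 3.71, 3.54, -3.59, -3.04, -2.68, -2.63, -2.80 and -2.95. Those of Birc5, H1f2, Acot1, Trp53inp1 and Serpine2 were 4.40, -4.21, -3.46, -4.00 and -3.27 there. For genes described further on, Tyms, Scd1, Shmt1, Chac1, Il24, Cd226, Batf3, Bcl6, Tcf7, Cxcr4 and Mx2, they were 2.66, 1.49, 1.87, 2.69, 2.33, 1.44, 2.62, -1.35, -0.88, -1.34 and -1.04 there, and each of these genes passed the threshold in that table too. In the same order they were smaller still with the background from all genes, at 2.30, 0.63, 1.41, 2.14, 1.52, 1.07, 2.26, -0.78, -0.72, -0.95 and -0.37, each past the threshold.

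**Figure D1:**
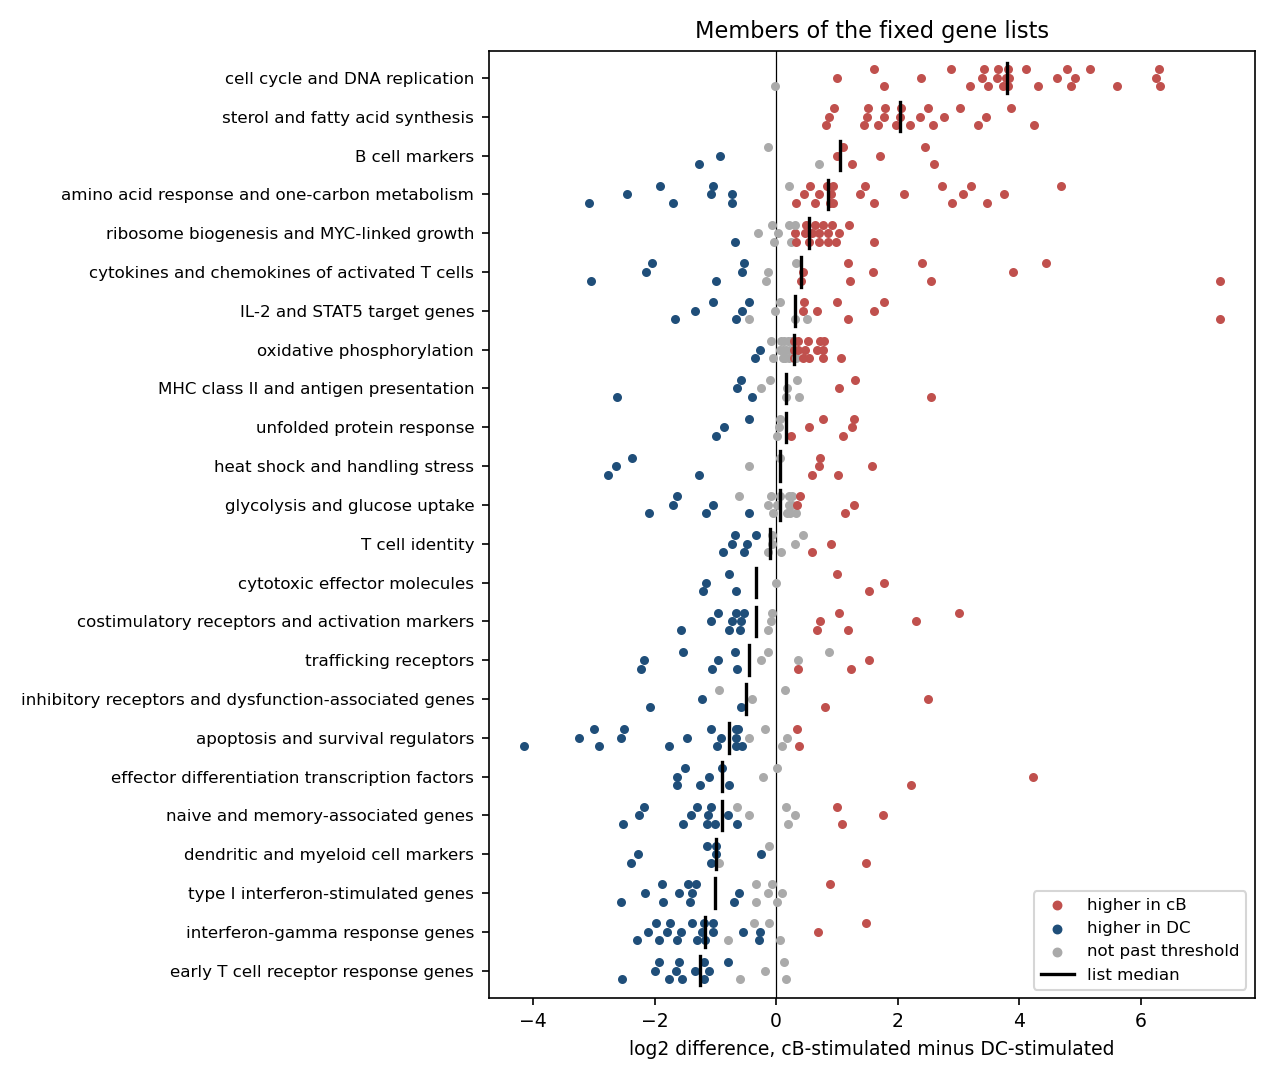
Log2 difference (cB minus DC, x axis) of every tested member of the 24 fixed lists with at least 3 tested members, 1 row per list, each point a gene coloured by its call and each black line the list's median. The cell cycle list has the highest median, 3.81, and the early T cell receptor response list the lowest, -1.26.

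Cell cycle and DNA replication genes rose in cB in 27 of the 28 tested, over all genes and adjusted over the list alone, with a median log2 difference of 3.81; Ccnd2 (-0.02) did not pass. With any 1 cB array left out, 19 of the 28 passed the detection filter, with a median between 3.81 and 3.97. The others needed every cB array to be tested, so their direction was partly set by the filter. Mcm5, a subunit of the replicative helicase, differed by 4.92 ± 0.10, and the thymidylate synthase gene Tyms, detected on 3 of the 4 DC arrays, by 4.31 ± 0.10. The list passed camera (adjusted p = 3.2e-17, and adjusted p = 0.019 with an estimated correlation), and its median was 2.37 with the background from all genes. All 22 sterol and fatty acid synthesis genes rose in cB (22 adjusted over the list alone), with a median of 2.05, among them Fdps at 4.25 ± 0.12, the desaturase gene Fads1 at 3.87 ± 0.12 and Sqle at 2.77 ± 0.09, while Scd1 was at least 8.54-fold higher. That list also passed (adjusted p = 8.6e-11, and adjusted p = 0.0068 with an estimated correlation); its median was 1.12 in the authors' gene-level table and 0.94 with the background from all genes. Of its 22 tested members, 17 passed the detection filter with any 1 cB array left out, with a median between 1.89 and 2.10. On the same cB arrays the B cell markers Fcmr and Cd79b were higher, by at least 5.96-fold and at least 4.83-fold. Their log2 differences were 1.08 and 0.97 in the authors' gene-level table and 0.42 and 0.33 with the background from all genes. Of 10 tested B cell markers 6 were higher in cB and 2 in DC, Pou2af1 (-1.27) among the 2.

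Of 30 genes of the amino acid response and carbon-unit metabolism list, 21 were higher in cB and 8 in DC, the same numbers adjusted over the list alone, with a median of 0.86. Among those higher in cB were Phgdh at 3.21 ± 0.10, Shmt1 at 3.08 ± 0.13, Psat1 at 2.74 ± 0.15 and Chac1, detected on 1 of the 4 DC arrays, at 4.70 ± 0.23. Ddit3 (-2.46) and Sesn2 (-3.08) were among those higher in DC. In the ribosome biogenesis and MYC-linked growth list, 17 of 25 genes were higher in cB and 1 in DC (17 and 1 adjusted over the list alone, median 0.54). Among its ribosome biogenesis genes were Noc4l at 1.03 ± 0.12 and Rrp12 at 0.85 ± 0.10. Its growth genes included Hspd1 at 1.62 ± 0.12 and Srm, the spermidine synthase gene, at 0.99 ± 0.11. Oxidative phosphorylation genes were higher in cB in 15 of 31 and in DC in 2 (15 and 2 adjusted over the list alone; median 0.29), with Atp5o at 1.07 ± 0.09. These 3 lists passed camera at the preset correlation (adjusted p = 0.0058, 0.0014 and 0.0092) and did not with an estimated correlation (adjusted p = 0.40 with an estimated correlation for each). The amino acid median was 0.54 in the authors' gene-level table and 0.50 with the background from all genes. All 3 lists lay on the side of the cB arrays, where 6 of 10 tested B cell markers were higher. Fcmr (at least 5.96-fold) and Cd79b (at least 4.83-fold) were among the 6. On the DC arrays 2 were higher, Pou2af1 (-1.27) among them. The glycolysis and glucose uptake list moved both ways, with 4 of 23 members higher in cB and 6 in DC. So did the unfolded protein response list (6 and 3 of 12) and the heat shock and handling stress list (5 and 4 of 11). None of these lists passed camera (adjusted p = 0.91, 0.29 and 0.99). Members higher in DC included Hif1a (-1.64) and Ankrd37 (-1.69), which are not glycolytic enzyme genes. In the stress list they included Txnip, Atf3 and Gadd45b (-2.37), which are not heat shock protein genes. For glycolysis and heat shock the median (0.056 and 0.071) was positive while the mean (-0.18 and -0.44) and the direction of the test were negative. Pfkfb4 (-2.09 ± 0.10), Txnip (-2.76 ± 0.14) and Atf3 (-2.64 ± 0.15) were higher in DC, and Pdia4 (1.28 ± 0.11) and Hspa8 (1.58 ± 0.11) in cB.

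Effector genes went both ways within each list. Of 19 tested cytokine and chemokine genes, 10 were higher in cB and 6 in DC, counts that also held adjusted over the list alone (median 0.41; camera adjusted p = 0.29). The cytokine median was 0.17 in the authors' gene-level table, 0.14 with the background from all genes and 0.076 with no detection filter. Beside Ifng, Il24 was at least 19.1-fold higher in cB, the chemokine gene Xcl1 differed by 3.90 and Il3 by 2.56 ± 0.19. Tnfsf8 (-3.05, detected on 2 of the 4 cB arrays), Ccl5 (-2.14), Lif (-2.05 ± 0.14) and, by less, Tnf (-0.54 ± 0.12) were higher in DC. Among 8 cytotoxic genes 3 were higher in cB and 4 in DC (3 and 4 adjusted over the list alone; camera adjusted p = 0.95), with a median of -0.33, a mean of 0.065 and a test on the DC side; this median was 0.0028 in the authors' gene-level table and -0.68, -0.51, -0.60 and -0.74 without cB replicate 1, 2, 3 and 4, each on 7 members. Gzmb, which encodes granzyme B, was undetected on the DC arrays and at least 2.83-fold higher in cB. Its log2 difference was only 0.65 in the authors' gene-level table and 0.18 with the background from all genes. Prf1, the perforin gene, was higher in cB by 1.00 ± 0.23, while Nkg7 (-1.20 ± 0.13) and Srgn (-1.15 ± 0.12) were higher in DC. In the IL-2 and STAT5 target list 8 of 19 were higher in cB and 6 in DC (8 and 6 adjusted over the list alone; camera adjusted p = 0.51), with Ccnd3 3.04-fold higher in cB, Il2ra at 0.68 ± 0.14 and Cish at -1.33 ± 0.14.

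**Figure D2:**
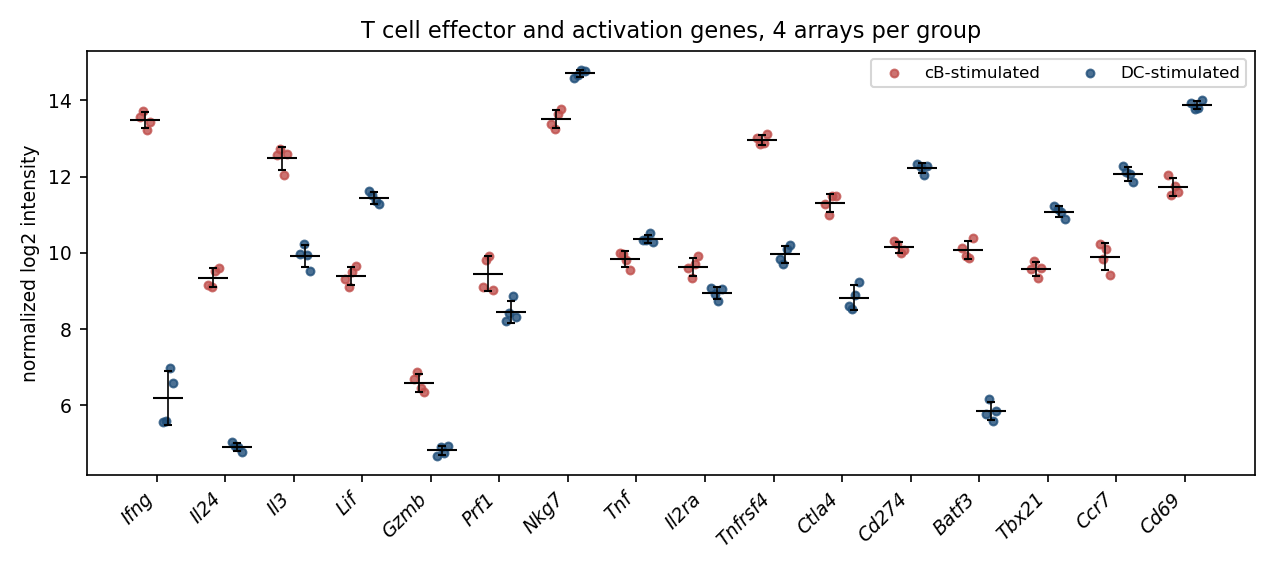
Normalized log2 intensity (y axis) of 16 effector and activation genes on each of the 4 cB and 4 DC arrays (points), with the group mean and SD in black. Ifng averages 13.48 on cB arrays and 6.18 on DC arrays, while Cd69, used for the sort, averages 11.72 and 13.88.

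Early T cell receptor response genes were higher in DC in 12 of 16 tested, with none higher in cB (13 adjusted over the list alone), and a median of -1.26. The transcription factor genes Jun (-2.54 ± 0.15) and Junb (-1.56 ± 0.12) and the phosphatase gene Dusp2 (-1.60 ± 0.12) were among them. The list passed camera at the preset correlation (adjusted p = 2.4e-04), and not otherwise (adjusted p = 0.094 with an estimated correlation); its median was -0.81 in the authors' gene-level table. On the same DC arrays 7 of 10 tested myeloid markers were higher, with Cd14 at least 5.03-fold and Il1b at least 4.49-fold. On the cB arrays 1, Fscn1 (1.47), was higher. Cd69 itself was higher in DC by a log2 difference of -2.15 ± 0.13; it checks the sort and is no finding. The sort gene Cd8a was undetected on all 8 arrays and Cd8b1 was bright on all, with a difference of -0.06 that did not pass.

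Costimulatory receptors and activation markers were higher in cB in 6 of 18 and in DC in 9 (6 and 9 adjusted over the list alone; median -0.34, mean 0.066, test on the DC side; camera adjusted p = 0.74), and the median was -0.17 in the authors' gene-level table. Tnfrsf4, which encodes OX40, was 8.02-fold higher in cB, Cd226 differed by 2.31 ± 0.14, and Cd27 (-1.08 ± 0.09) and Slamf7 (-1.56 ± 0.15) were higher in DC. Of 8 inhibitory receptor and dysfunction genes, 2 were higher in cB and 3 in DC (2 and 3 adjusted over the list alone; camera adjusted p = 0.51). Ctla4 was higher in cB (2.50 ± 0.18), and Cd274, which encodes PD-L1, and Btla were higher in DC (-2.08 ± 0.11 and -1.22 ± 0.13). Pdcd1 was detected on 1 cB array and was not tested.

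Of 20 naive and memory-associated genes, 12 were higher in DC and 3 in cB (12 and 3 adjusted over the list alone; median -0.90), among them the repressor gene Bcl6 (-2.51 ± 0.19), the homing receptor gene Ccr7 (-2.17 ± 0.18) and Tcf7 (-1.30 ± 0.15); the list did not pass camera (adjusted p = 0.055, and adjusted p = 0.40 with an estimated correlation). At the preset correlation it passed under 10 of 18 alternatives, among them the authors' gene-level table (adjusted p = 0.035), with adjusted p at most 0.084, and its median was -0.41 with the background from all genes. These genes too were measured on DC arrays where Cd14 was at least 5.03-fold and Il1b at least 4.49-fold higher. Those markers differed by -0.97 and -0.92 in the authors' gene-level table and by -0.36 and -0.33 with the background from all genes. The marker Fscn1 (1.47) went the other way. Effector transcription factor genes were higher in DC in 7 of 11 and in cB in 2 (7 and 2 adjusted over the list alone; camera adjusted p = 0.22). Batf3 (4.23 ± 0.16) and Batf (2.22 ± 0.14) were higher in cB, and Tbx21, which encodes T-bet (-1.51 ± 0.12), and Irf4 (-1.10 ± 0.10) in DC. Among 14 trafficking receptors 3 were higher in cB and 7 in DC (3 and 7 adjusted over the list alone; camera adjusted p = 0.36), with Cxcr4 at -2.22 ± 0.30 and Cxcr5 at -1.53 ± 0.21.

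Interferon-gamma response genes were higher in DC in 18 of 24 and in cB in 2 (19 and 2 adjusted over the list alone), with a median of -1.18, although Ifng itself was higher in cB. Irgm2 (-2.11 ± 0.10) and Igtp (-1.74 ± 0.11), both interferon-inducible GTPase genes, Tap1, a peptide transporter gene (-1.98 ± 0.13), and Irf1 (-1.80 ± 0.12) were examples. Type I interferon-stimulated genes were higher in DC in 11 of 18 and in cB in 1 (11 and 1 adjusted over the list alone; median -1.01), with Irf9 at -1.87 ± 0.15 and Mx2 at least 5.55-fold higher. Both lists passed camera at the preset correlation (adjusted p = 1.7e-04 and 0.005), and neither did otherwise (adjusted p = 0.36 and 0.40 with an estimated correlation). Their medians were -0.71 and -0.66 in the authors' gene-level table and -0.50 and -0.20 with the background from all genes. With no detection filter they were -1.04 on 28 members and -0.14 on 31. Without DC replicate 4 the type I list no longer passed (median -0.50, adjusted p = 0.061), and without DC replicate 1 its median was -0.57. Apoptosis and survival regulators were higher in DC in 16 of 22 and in cB in 2 (16 and 2 adjusted over the list alone; median -0.78). Phlda3 (-4.16 ± 0.13), Cdkn1a, a cyclin-dependent kinase inhibitor gene (-3.24 ± 0.15), the death receptor gene Fas (-3.00 ± 0.13) and Ei24 (-2.55 ± 0.11) were among them, and they are known p53 targets. This list passed camera both ways (adjusted p = 2.0e-04, and adjusted p = 0.043 with an estimated correlation). Its mean, -1.24, was larger in size than its median, and it shares 8 members with the p53 target list described further on. Whether it passes without them was not tested. On the same DC arrays the myeloid markers Cd14 and Il1b were at least 5.03-fold and at least 4.49-fold higher than on cB arrays, where neither was detected. Their log2 differences were -0.97 and -0.92 in the authors' gene-level table and -0.36 and -0.33 with the background from all genes. Of 10 tested myeloid markers 7 were higher in DC and 1, Fscn1 (1.47), in cB.

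Markers of the stimulator cells followed the stimulator in part. Of 10 tested B cell markers, 6 were higher in cB and 2 in DC (7 and 2 adjusted over the list alone; median 1.05; camera adjusted p = 0.13), with Pou2af1 higher in DC (-1.27 ± 0.16). The B marker median turned to -1.06, -0.93, -1.05 and -0.51 without cB replicate 1, 2, 3 and 4, when 2, 3, 2 and 4 members passed the detection filter. It was 0.37 in the authors' gene-level table and 0.10 with the background from all genes. With no detection filter the B marker list passed camera (adjusted p = 0.0089), while its median was only 0.21 on 22 members. Of 10 tested dendritic and myeloid markers, 7 were higher in DC and 1 in cB (7 and 1 adjusted over the list alone; median -0.99; camera adjusted p = 0.066, and adjusted p = 0.40 with an estimated correlation), and this median was -0.36 in the authors' gene-level table and -0.19 with the background from all genes. The list passed at the preset correlation under 3 of 18 alternatives, with adjusted p at most 0.33 over all of them. The 3 were the replicate block (adjusted p = 0.042), equal medians (adjusted p = 0.031) and no detection filter (adjusted p = 0.0048). With no detection filter the median was only -0.17 on 34 members. Ctss, detected on 3 of the 4 cB arrays, differed by -1.07 ± 0.16, Fscn1, an actin-bundling gene of mature dendritic cells detected on 3 of the 4 DC arrays, by 1.47 ± 0.21, and Cst3 by -0.26 ± 0.10, a call made under 8 of 18 alternatives. Of 13 MHC class II and shared presentation genes, 3 were higher in cB and 4 in DC (3 and 4 adjusted over the list alone; median 0.16, and 0.052 in the authors' gene-level table; camera adjusted p = 0.91), with Cd74 at 2.55 ± 0.31, Cd86 at 1.04 ± 0.23 and Cd80 at -2.62 ± 0.19. T cell identity genes were higher in cB in 2 of 14 and in DC in 6 (3 and 6 adjusted over the list alone; median -0.11; camera adjusted p = 0.64), with Thy1 at 0.90 ± 0.14 and Zap70 at -0.88 ± 0.11. The identity median turned to 0.031 without cB replicate 4 and to 0.0015 with array weights, and it was -0.21, -0.20 and -0.20 without cB replicate 1, 2 and 3 and -0.19 without DC replicate 2. Among markers of NK, CD4 and gamma-delta T cells 2 were tested, and Il18r1 was at least 1.91-fold higher in cB. Klrd1 differed by -0.67 ± 0.31 (adjusted p = 0.085). It was past the threshold under 4 of 18 alternatives, among them the replicate block (adjusted p = 0.0012). In the authors' gene-level table Fscn1, Ctss, Cd80, Cd86 and Il18r1 differed by 0.61, -0.36, -1.47, 0.38 and 0.35, each past the threshold. With the background from all genes they differed by 0.23, -0.11, -0.94, 0.13 and 0.093, each past the threshold too.

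**Figure D3:**
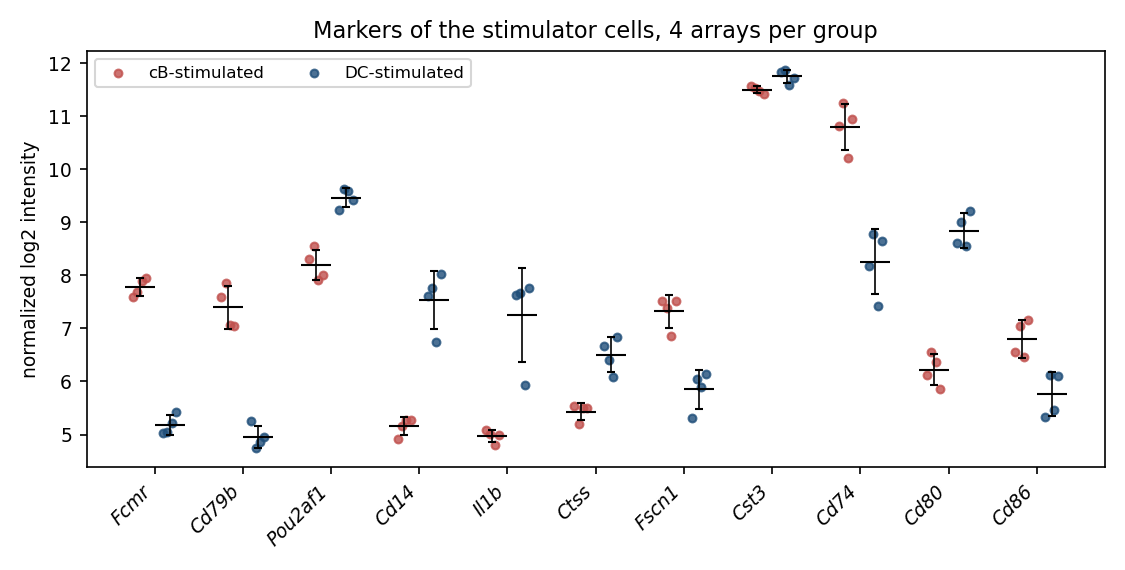
Normalized log2 intensity (y axis) of 11 markers of B cells, dendritic cells and antigen presentation on each of the 4 cB and 4 DC arrays (points), with the group mean and SD in black. Fcmr averages 7.78 on cB arrays and 5.18 on DC arrays, and Cd14 averages 5.15 and 7.54.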

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

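In 16 of 302 groups of 4 arrays, 1 array lay far from the other 3: its gap to the nearest of them, as a share of the group's range, was above Dixon's critical value. Chance gives this in about 1 group in 20, so chance alone can give a number of this size. Of the 16, 5 came from DC replicate 3, 4 from cB replicate 1 and 4 from cB replicate 2. On cB arrays the shares were 0.854 for Kif22, 0.834 for Zfp750, 0.864 for Mx2 and 0.837 for Atf3 (replicate 1), 0.924 for Atp5c1, 0.848 for Pdia4, 0.838 for Phlda3 and 0.887 for Ctss (replicate 2), and 0.972 for Serpine2 (replicate 4). On DC arrays they were 0.861 for Rad54b and 0.888 for the mean of the sterol and fatty acid list (replicate 1), and 0.856 for Ankrd37, 0.889 for Phgdh, 0.868 for Cxcr5, 0.931 for Il1b and 0.841 for the mean of the interferon-gamma response list (replicate 3). The Il1b level on DC replicate 3 was 5.94, where the other 3 DC arrays averaged 7.69.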

How the results depend on the processing

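The alternative with the background from all genes' detection p-values was added after the data were seen; the others were planned. The count of 4397 genes stayed within 1.5 times under every alternative run, from 3202 with a detection p below 0.01 on all arrays to 6216 probes in the authors' probe-level table, and from 3980 to 4181 with 1 array left out. The size-filtered counts moved further, from 1755 (864 higher in cB, 891 in DC) to 923 (472 and 451) with no background correction, 960 (497 and 463) in the authors' gene-level table, 1083 (509 and 574) with detection at p below 0.01 on all arrays, where 4717 genes were tested, and 962 (476 and 486) with the background from all genes. Differences of dim genes are therefore less certain in size than in direction. Of the values of named genes under alternatives, 1989 kept direction and call, 4 gained a call and 11 lost it (10 of them Cst3), and 0 changed direction. Among lists 414 kept both, 14 gained a call and 7 lost it, 6 of these with the estimated correlation. The direction of camera turned 18 times, in lists that had passed in neither setting. For heat shock the median was then 0.068 without background correction, 0.13 in the authors' gene-level table, 0.071 with no detection filter, 0.33 with detection at p below 0.01 and 0.076 with the background from all genes, and it ranged from 0.0077 to 0.14 with 1 array left out. For glycolysis it was 0.11 with detection at p below 0.01 and ranged from 0.023 to 0.15 with 1 array left out, the test turning without cB replicate 2. For MHC class II it was -0.24 with detection at p below 0.01 and ranged from -0.082 to 0.26 with 1 array left out, the test turning without cB replicate 2, cB replicate 4 or DC replicate 1. The cause was not tested. For B cell markers the median turned without any of the cB arrays, to -1.06, -0.93, -1.05 and -0.51 without cB replicate 1, 2, 3 and 4, because genes seen only on cB arrays then fail the filter and 2, 3, 2 and 4 members remain; it was -1.09 on 2 members with detection at p below 0.01. Lists with fewer than 3 members were not tested. Without a DC array it was at most 1.15. The groups share replicate numbers, and the sample numbers in the labels alternate between DC and cB in the same order, but no label says that a number marks a shared animal, culture or batch. The deviations of same-numbered arrays from their group means correlated across genes at 0.113, 0.128, 0.175 and 0.0824, genes not being independent replicates, and all 8 arrays correlated best with their own number, a hint from the data. With the replicate block 4431 genes passed in place of 4397, and 1757 in place of 1755 with the size filter; Klrd1 (adjusted p = 0.0012) and the dendritic and myeloid list (adjusted p = 0.042 at the preset correlation; without the block, adjusted p = 0.40 with an estimated correlation) gained a call and Cst3 (adjusted p = 0.054) lost it. The rules for several probes per gene and the slide as a block were not run, since the tables hold 1 row per gene or no gene names, and no slide. Signal near background limits the size of large differences, so bounds are given under the main setting where a group was undetected.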

Other observations

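The gene lists in this part were written after the values had been seen, and so were the tests of carried-over RNA, of the stage of the cells, of receptor mRNA and of type I interferon; the tests by array splits, by alternatives and without the top genes were fixed before their results were seen. Core histone genes, taken by name, were higher in cB in 33 of 35 tested and higher in DC in 1 (33 and 1 adjusted over the list alone), with a median log2 difference of 2.51 (camera adjusted p = 8.1e-14, and adjusted p = 0.033 with an estimated correlation). H3c1 (4.29) and H2ac11 (4.46) were among them and H2ac18 (-3.39) was the exception; their sequences are alike, so single members are uncertain. Known p53 target genes were higher in DC in 30 of 33 and in cB in 2, Ddb2 (1.55) and Fdxr (0.66), with a median of -2.50 (camera adjusted p = 2.2e-12, and adjusted p = 0.033 with an estimated correlation). Mdm2, the p53 ubiquitin ligase gene (-2.78), Bbc3 (-2.91), Ccng1 (-2.77) and Plk2 (-4.24) were examples, and 10 members of this list are also in a fixed list. Lysosome and autophagy genes split, 8 higher in cB and 15 in DC of 33 (camera adjusted p = 0.17). Of 7 NRF2 targets 3 were higher in cB and 0 in DC, and the list did not pass (camera adjusted p = 0.20).

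Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many as 4397 changed genes. The highest of the others gave 1. Every other split mixes the groups, so the group gap enters its spread and a low count was fixed in advance. The splits therefore cannot exclude chance, or a difference in culture or batch between the groups.

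Cell cycle genes were higher in cB. B cell RNA carried through the sort for CD8 and CD69 cannot be told apart from a change in the T cells: of 22 B cell markers measured, 7 were undetected on all 4 cB arrays and 8 were detected on all 4, and an undetected probe decides little where that of Cd8a, a sort gene, was undetected too. Among abundant genes of these stimulators Cd74 differed by 2.55, and H2-Ab1 lay at 10.28 in cB and 10.11 in DC. An earlier stage of the DC-stimulated cells at the single time sampled also stays open, with early response genes at a median of -1.26, a list that did not pass with an estimated correlation (adjusted p = 0.094) and had a median of -0.81 in the authors' gene-level table. A difference in T cell proliferation between stimulators is the biological hypothesis, and it was not tested.

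The higher p53 targets in DC may reflect p53 activity in the T cells, a hypothesis that was not tested. For the members chosen, normalization as the whole cause is argued against, since the median stayed at -2.08 or lower under 18 alternatives. The camera p of at most 1.5e-10, at the preset correlation, adds nothing, since the list was written after the values had been seen. Selection of the list stays open, since all its members were chosen after the values had been seen: the 18 members outside the 90 genes most raised in DC had a median of -1.55 (camera p = 0.0041 at an estimated correlation), but they were open to the same choice. Dendritic cell RNA as a part of the cause cannot be told apart: 19 of 34 myeloid markers were undetected on all 4 DC arrays. This decides little for the reason given for Cd8a, and Cst3, the brightest marker, differed by -0.26. As the whole cause, carried RNA would make the p53 genes follow the myeloid markers from array to array. The myeloid marker mean was 7.92, 8.08, 7.48 and 8.30 on DC replicates 1 to 4 (SD 0.34). The p53 list mean was 10.65, 10.71, 10.67 and 10.66 there (SD 0.027), which argues against dendritic cell RNA as the whole cause for this list.

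Interferon-gamma response genes were higher in DC although Ifng was higher in cB. Less receptor mRNA in cB-stimulated cells is a candidate explanation: Ifngr1 differed by -3.22 and Ifngr2 by -1.10, both past the threshold, but Ifngr1 had been seen before the test and mRNA is not the receptor. Type I interferon in the DC cultures cannot be told apart, since the type I list had a median of -1.01 and did not pass with an estimated correlation (adjusted p = 0.40). The response list itself did not pass with an estimated correlation either (adjusted p = 0.36).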
